A study of Homo sapiens with 12 samples.

How the data were processed

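Total RNA was sequenced from human myoblasts. It was extracted with a column kit that includes DNase treatment, and libraries were made by standard Illumina protocols; any poly(A) selection or ribosomal RNA removal was not given in the sources used here. Per the labels, cells received 50 nM of a control siRNA or of an siRNA against the long non-coding RNA lncFAM 24 h before differentiation was induced by high density and a change to low-serum medium. The 12 libraries fall into 4 groups of 3, by siRNA (control or lncFAM) and by time (16 h or 48 h). The labels do not say from which moment the hours are counted, nor whether the 3 libraries of a group came from separate cultures, so the replicates were treated as independent without that being stated. The labels name 1 lncFAM siRNA arm and describe no rescue.

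The authors deposited one table of raw counts per library, with a whole-number read count for each Ensembl gene ID and no normalization. The submitters' processing notes list bcl2fastq 2.20.0.422, cutadapt, STAR 2.4.0j, featureCounts 1.6.4 and the human build hg19. The version of cutadapt, the annotation release, the strand setting and the handling of reads that map to several places were not given in the sources used here. The 4 annotated copies of the U1 small nuclear RNA tested held counts within 0.304% of each other in every library, so reads that map to several copies appear to have been counted at each; values of near-identical gene copies are therefore not independent.

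Each file held the same 57773 gene IDs. Symbols were paired through the reference name tables for 39539 IDs, and 52338 IDs were found in GENCODE 29, which gave gene type, strand, exons and the order of neighbours. A further 5435 IDs were in neither and held 18.0% of all counts, of which 16.6% lay on 2 IDs. Because the files rest on hg19 and the annotation used here on a later build, no positions are given, only chromosome, neighbour order and gene type. lncFAM was taken from the row ENSG00000268518, which the reference tables tie to that name as a synonym of the RefSeq gene MYREM.

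Total counts lay between 63267897 and 93768909 in 11 libraries and at 256366866 in control 48 h replicate 3. Protein-coding genes took 44.1% to 55.1% of the counts, and the mitochondrial ribosomal RNA gene MT-RNR2 took 8.8% to 17.9%. Pearson correlations of log2 CPM (counts over TMM-scaled totals) across genes were 0.947 to 0.988 within groups and 0.866 to 0.965 between groups. Genes are not independent replicates. No library was a copy of another. Intervals and floors from counts cover counting error only.

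Counts were fitted with the quasi-likelihood method of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with TMM scaling, genes kept by filterByExpr on the 4 groups (23189 genes tested), and one mean per group over all 12 libraries. The contrasts were lncFAM minus control siRNA at 16 h and at 48 h, 48 h minus 16 h with each siRNA, and the difference of the siRNA effects (48 h minus 16 h), called the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Adjusted p values of genes in the text come from this fit; log2 fold changes carry the standard error (SE) of the fit, and CPM values are group means with the standard deviation (SD) over n = 3 libraries.

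Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and with a correlation estimated for each list, and with fry, each adjusted over the 26 lists of a contrast. The lists were myogenic transcription factors, sarcomere proteins, fusion and membrane proteins, calcium handling, the neuromuscular junction, muscle metabolism, mitosis, DNA replication, p53 targets, interferon-stimulated genes, inflammatory genes, extracellular matrix, markers of fibroblasts, smooth muscle, endothelium, leukocytes and adipocytes, the unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, the Notch, Wnt and TGF-beta pathways, RNA-binding proteins of the hnRNP type, ribosomal proteins, mitochondrially encoded genes and immediate early genes. Some members stand in more than one list. Members called are counted over all genes tested and, where stated, adjusted over the list alone (list-wise). A list that missed its camera test is described by its called members only. Genes whose gene body lies within 500 kb of MYBPC2 formed a further list.

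The comparisons, tests, lists, the rule for naming genes and most alternatives were fixed before the data were examined. By that rule the text may name lncFAM, MYBPC2 and HNRNPL, which the study's title names; per contrast the 10 genes with the largest change each way (5 each way for the interaction) among called genes with a mean log2 CPM of at least 2, groups that do not overlap (not asked of the interaction) and an established symbol; up to 4 members of each list with the smallest adjusted p; and MYOG, MYOD1, PAX7, MYH3, MYH8, CKM and MKI67 as landmarks. Genes outside the rule are marked as chosen after their values were seen.

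The overlap of the time and siRNA effects was set against 20 simulations of unchanged groups that share libraries in the same way. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a CPM of at least 1 in at least 3 libraries, only the libraries of the groups compared, a replicate block, each library left out in turn, an adjusted p under 0.01, a minimum absolute log2 fold change of 1, a window of 1 Mb, the estimated correlation and, for the lists, a replicate block, RLE scaling and camera on voom weights. After the data were seen, 5 more were added: protein-coding genes only, control 48 h replicate 3 thinned to the median total, 2 replicates per group, a trend on transcript length and GC content removed, and each library's slope on transcript length as a covariate. When 1 library is left out, the other 2 of its group are assumed to vary like the other groups.

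The pipeline was tested on simulated counts with these depths and spreads. Of 100 genes changed 2-fold, 18, 8, 11 and 12 were called in the siRNA effects at 16 h and 48 h and the time effects with control and lncFAM siRNA, and 3 in the interaction; of 100 changed 4-fold, 77, 72, 76, 73 and 45 were called. Small changes are often missed, and a gene not called is not shown to be unchanged. A raised list of 40 genes was called in each contrast, and 0 of 20 unchanged lists were, with correlated genes untested. Further software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.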

Results

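Gene expression was measured by RNA sequencing in human myoblasts, the precursors of muscle fibres, treated with a control siRNA or an siRNA against the long non-coding RNA lncFAM. The 12 libraries form 4 groups of 3, namely each siRNA at 16 h and at 48 h of the differentiation experiment. Total counts were 93457406, 72178804 and 93768909 with control siRNA at 16 h, and 79309210, 63733435 and 66084289 with lncFAM siRNA at 16 h. At 48 h they were 63267897, 75089746 and 256366866 with control siRNA and 72225619, 67404988 and 63868821 with lncFAM siRNA. The study's title sets its purpose as the recruitment of the RNA-binding protein HNRNPL by lncFAM to the promoter of MYBPC2, and its design as finding genes that differ after lncFAM is silenced. Levels below are mean CPM ± SD over n = 3 libraries. A value such as -1.78 ± 0.225 after a gene is its log2 fold change with the approximate SE derived from the edgeR fit, from 3 libraries per group.

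lncFAM itself, ENSG00000268518, a long intergenic non-coding RNA gene on the minus strand of chromosome 19, was 13.5-fold lower after its siRNA at 16 h. It stood at 0.292 ± 0.23 CPM against 4.09 ± 1.4 CPM with control siRNA (log2 fold change -3.75, SE 0.5, edgeR adjusted p = 0.000145). At 48 h it was 17.1-fold lower, at 1.06 ± 0.18 against 18.1 ± 4.9 CPM (log2 fold change -4.09, SE 0.48, edgeR adjusted p = 4.25e-05). MYBPC2, which encodes fast myosin-binding protein C of the sarcomere, was 6.36-fold lower at 16 h, at 1.85 ± 1.4 against 11.8 ± 6 CPM (log2 fold change -2.67, SE 0.574, edgeR adjusted p = 0.00505). At 48 h MYBPC2 stood at 68.4 ± 26 against 210 ± 16 CPM (log2 fold change -1.62, SE 0.541, edgeR adjusted p = 0.0427). HNRNPL fell at 16 h, from 197 ± 7.7 to 112 ± 3.2 CPM (log2 fold change -0.81, SE 0.173, edgeR adjusted p = 0.00459). It was not called at 48 h, at 166 ± 30 against 148 ± 5.4 CPM (log2 fold change 0.17, SE 0.172, edgeR adjusted p = 0.497). That value was -0.022 without lncFAM 48 h replicate 3 and -0.095 with the length and GC trend removed.

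The difference between the siRNA effects at 48 h and 16 h was not called for HNRNPL (log2 0.99, SE 0.243, edgeR adjusted p = 0.0509). The same held for MYBPC2 (log2 1.05, SE 0.76, edgeR adjusted p = 0.488) and lncFAM (log2 -0.34, SE 0.655, edgeR adjusted p = 0.81). For HNRNPL it was called by DESeq2 (adjusted p = 0.0173), limma-voom (0.0413), with a replicate block (0.0492) and without lncFAM 48 h replicate 2 (0.0159). It was also called with control 48 h replicate 3 thinned (0.0491) and with the length and GC trend removed (0.0203). For lncFAM the difference was 0.37 without lncFAM 16 h replicate 1. All 626 lncFAM exon bases lie inside EMC10 exons on the opposite strand. Whether strands were kept apart is not given, so the lncFAM row may hold EMC10 reads. EMC10 was not called at 16 h (-0.34 ± 0.255, adjusted p = 0.408) or 48 h (-0.13 ± 0.255, adjusted p = 0.742). ENSG00000268854, also opposite EMC10 exons, had like values (-0.35 and -0.17). The MYBPC2 call at 48 h rested on single libraries. It ended without control 16 h replicate 1 (adjusted p = 0.0529), lncFAM 16 h replicate 1 (0.0574), control 48 h replicates 1 (0.0536), 2 (0.0968) or 3 (0.0642). It also ended without lncFAM 48 h replicates 1 (0.117) or 2 (0.0534), and with the length slope as a covariate (0.0581).

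**Figure D1:**
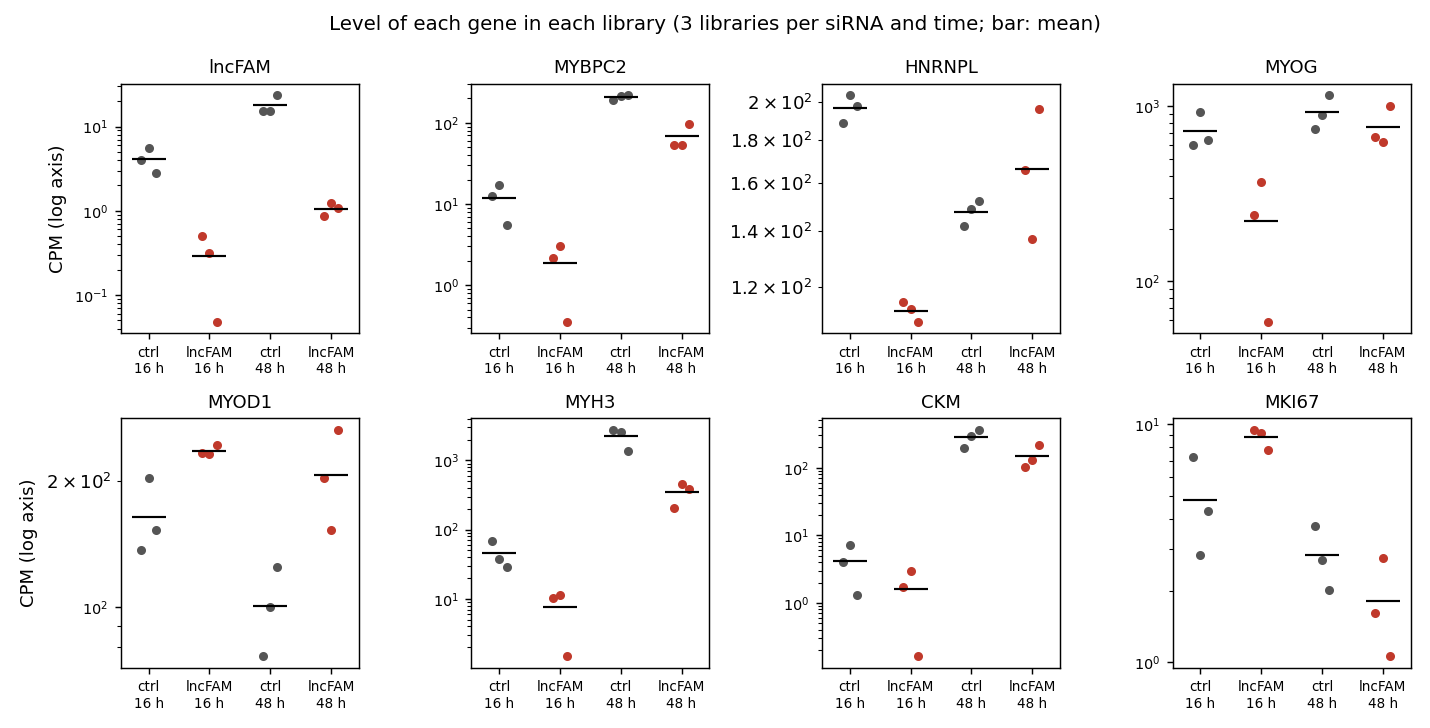
CPM (log axis) of lncFAM, MYBPC2, HNRNPL, MYOG, MYOD1, MYH3, CKM and MKI67 in each of the 12 libraries; points are libraries and bars are means of the 3 libraries of each siRNA and time. Mean lncFAM fell from 4.09 to 0.292 CPM at 16 h and from 18.1 to 1.06 CPM at 48 h, while mean MYBPC2 rose with time with both siRNAs.

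Genes near MYBPC2 were compared because the study's title places the action of lncFAM at that promoter. The reference annotation, on a later genome build than hg19, puts 53 genes within 500 kb of MYBPC2 on chromosome 19, of which 21 were tested. At 16 h edgeR called 5 of these lower and 0 higher, over all genes tested and adjusted over the list alone, and the 1 Mb window below held 4 risers. The 5 were the siRNA's own target lncFAM, MYBPC2, SPIB, ENSG00000142539 and SHANK1. SPIB, an ETS-family transcription factor, lies next to MYBPC2 among the tested genes, on the same strand, and fell from 8.76 ± 1.4 to 0.403 ± 0.22 CPM (log2 fold change -4.43, SE 0.424, edgeR adjusted p = 8.38e-06). At 48 h SPIB stood at 1.14 ± 0.52 against 10.5 ± 1.7 CPM (log2 fold change -3.20, SE 0.39, edgeR adjusted p = 5.89e-05). ENSG00000142539, a protein-coding gene next to SPIB that shares 839 exon bases with it, fell at both times (-1.66 ± 0.367 and -1.63 ± 0.364), and SHANK1 fell at 16 h (-1.36 ± 0.416). At 48 h 4 genes rose, namely VRK3 (1.05 ± 0.225), NR1H2, NAPSA and C19orf48P. The 4 that fell were lncFAM, MYBPC2, SPIB and ENSG00000142539, again with equal counts adjusted over the list alone. The MYBPC2 call at 48 h ended without any 1 of the 7 libraries named above. Within 1 Mb 71 genes were tested, and 4 rose and 6 fell at 16 h, against 13 and 4 at 48 h. SPIB and the other neighbours were named after their values were seen.

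**Figure D2:**
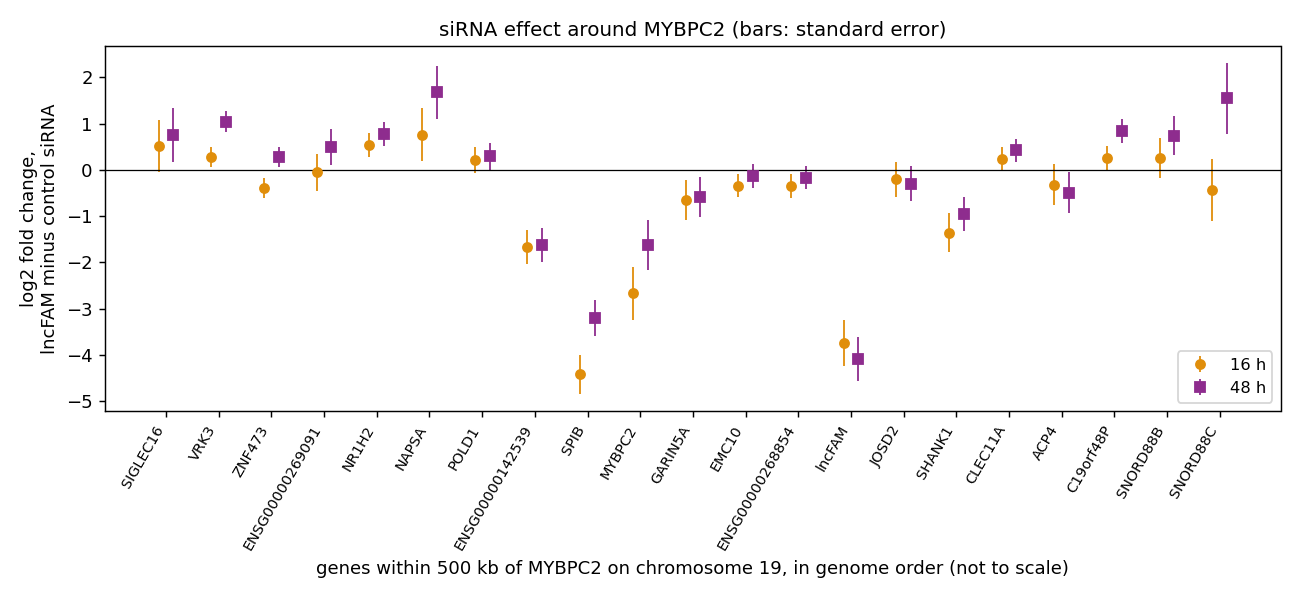
Log2 fold change (lncFAM siRNA minus control siRNA) with its SE for the 21 tested genes within 500 kb of MYBPC2, in genome order, at 16 h and 48 h with 3 libraries per group. SPIB, at -4.43 and -3.20, and lncFAM, at -3.75 and -4.09, lie lowest.

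The comparison of lncFAM siRNA with control siRNA at 16 h asks which genes differ early after silencing. Genes of the interferon response stood out. MX1, an antiviral GTPase, rose from 5.27 ± 1.2 to 1940 ± 65 CPM (8.52 ± 0.363), and OAS1, which makes the signal that activates an RNA-degrading enzyme, rose from 1.72 ± 0.61 to 506 ± 14 CPM (8.20 ± 0.318). IFI27 (9.96 ± 0.394), BST2 (9.60 ± 0.484) and IFITM1 (6.95 ± 0.25) rose as well, and RSAD2, an antiviral enzyme, went from 0.0275 ± 0.031 to 201 ± 57 CPM. Each of the 43 tested interferon-stimulated genes rose, also when adjusted over the list alone. Their median log2 fold change was 5.83 (camera adjusted p = 1.41e-54; 0.0036 with estimated correlation). In the control libraries 3 members had no counts, and the median stays 5.83 with these set at 3 counts over the group. F13A1, a coagulation factor subunit, fell from 403 ± 170 to 28.6 ± 17 CPM (-3.81 ± 0.461). AIF1L, an actin-binding protein (-4.64 ± 0.507), DHRS3, which reduces retinaldehyde (-4.60 ± 0.289), CCDC88C (-4.43 ± 0.464) and PRKAG3, a muscle subunit of the energy sensor AMPK (-3.79 ± 0.47), were also among the largest falls.

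The 4 muscle lists that passed camera at 16 h had negative medians. With an estimated correlation the 14 lists called at 16 h other than the interferon-stimulated one lost their calls (adjusted p between 0.196 and 0.612). By fry, which does not compare a list with other genes, the sarcomere (adjusted p = 0.0797), muscle metabolism (0.131), mitosis (0.114), oxidative phosphorylation (0.142), hnRNP (0.11) and mitochondrially encoded (0.0559) lists missed and p53 targets passed (0.0109). In each of the 4 muscle lists lncFAM 16 h replicate 3 stood lowest. Median log2 CPM of the sarcomere list was 0.57 in that library, 1.92 and 2.29 in the other lncFAM siRNA libraries and 3.07, 2.96 and 2.01 with control siRNA, so that the groups overlapped, as they did for fusion and metabolism. MYOG stood at 58.8 CPM in that library, against 239 and 367 CPM in the others. Of 71 sarcomere genes 21 fell and 5 rose (23 and 5 adjusted over the list alone, list-wise below). Their median was -0.90 (camera adjusted p = 1.89e-05). The 5 sarcomere genes higher were 2, 1 and 1 without control 16 h replicates 1, 2 and 3, and 2 and 2 without lncFAM 16 h replicates 1 and 2. ANKRD1, a stress-responsive titin partner, fell from 292 ± 84 to 56.9 ± 12 CPM (-2.36 ± 0.278), cardiac-type troponin TNNT2 from 2150 ± 150 to 626 ± 170 CPM (-1.78 ± 0.225) and tropomyosin TPM1 by -1.84 ± 0.246. Of the calcium-handling genes 13 of 28 fell and 1 rose (14 and 1 list-wise), led by sarcalumenin SRL (-3.06 ± 0.411) and the sodium channel SCN4A (-3.06 ± 0.355). Their median was -0.93, or -0.90 with a member of at most 3 counts in each group left out (camera adjusted p = 1.89e-05). Among 30 fusion and membrane genes 9 fell and 1 rose (11 and 1 list-wise), with a median of -0.28 (camera adjusted p = 0.0269). The fusion factor myomaker MYMK (-1.98 ± 0.303) and the adhesion molecule NCAM1 (-2.0 ± 0.378) fell. Muscle metabolism had 4 members lower and 3 higher of 26 (10 and 3 list-wise), among them FABP3, a fatty acid carrier (-3.06 ± 0.463), and hexokinase HK2 (2.30 ± 0.22). The median of that list was -0.52 (camera adjusted p = 0.0315). The embryonic myosin MYH3 fell from 45.3 ± 21 to 7.71 ± 5.4 CPM (-2.55 ± 0.597, adjusted p = 0.00859). MYOG, a driver of terminal differentiation, fell from 719 ± 180 to 222 ± 150 CPM (-1.70 ± 0.47, adjusted p = 0.0219). MYOD1 (0.52 ± 0.243, adjusted p = 0.164), MYH8 (-1.48 ± 0.762, 0.21), CKM (-1.36 ± 0.709, 0.218) and the cycling marker MKI67 (0.87 ± 0.372, 0.127) were not called. MKI67 was called without control 16 h replicate 1 (adjusted p = 0.0398), with only the groups compared (0.0329) and with the length and GC trend removed (0.0325). MYOD1 was called with that trend removed (0.00171) and with the length slope as a covariate (0.0033), and MYH8 with that covariate (0.0152) and a replicate block (0.0339). Without a filter MKI67 (0.0385), MYH8 (5.88e-06) and CKM (4.67e-05) were called, and CKM also with 2 replicates per group (0.0155). PAX7, a marker of muscle stem cells, had no counts in the lncFAM siRNA libraries at 16 h, against 0.0368 ± 0.034 CPM, and was not called (adjusted p = 0.0885). It was called by DESeq2 (adjusted p = 0.0372), without a filter (0.0361) and without control 16 h replicate 2 (0.0458). The MYOG call ended without control 16 h replicate 2 (adjusted p = 0.0674) or lncFAM 16 h replicate 1 (0.0632). The fusion genes lower were 5 without lncFAM 16 h replicate 1, and the calcium genes lower 8 without control 16 h replicate 2. The muscle metabolism call ended without control 16 h replicate 2 (0.154) or lncFAM 16 h replicate 3 (0.103) and with the length slope as a covariate (0.158).

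Other lists also passed camera at 16 h. Cholesterol synthesis fell, with 14 of 25 members lower and 0 higher (15 and 0 list-wise), among them ACAT2 (-1.73 ± 0.197) and DHCR7 (-1.73 ± 0.266). Its median was -0.93 (camera adjusted p = 9.33e-08). Again lncFAM 16 h replicate 3 stood lowest, at a median log2 CPM of 4.39 against 5.46 and 5.68, with control siRNA at 6.68, 6.45 and 5.66. Library medians of the 2 groups also overlapped for the hnRNP, mitochondrially encoded, unfolded protein and glycolysis lists. Ribosomal protein genes had 11 of 41 lower and 0 higher (14 and 0 list-wise), with a median of -0.48 (camera adjusted p = 1.66e-07). Mitochondrially encoded genes had 4 of 13 lower and 0 higher (7 and 0 list-wise), led by MT-CO3 (-1.47 ± 0.217). They had a median of -0.61 (camera adjusted p = 0.0022). Genes of the hnRNP type had 7 of 31 lower and 1 higher by both adjustments, with the splicing factor RBFOX1 lower (-2.21 ± 0.274) and PTBP1 higher (0.99 ± 0.197). Their list had a median of -0.39 (camera adjusted p = 0.00339). Inflammatory genes rose, 9 of 21 higher and 2 lower by both adjustments, with a median of 1.08 (camera adjusted p = 0.000787). IL6 reached 1.65 ± 0.49 CPM from 0.0334 ± 0.041, and the growth factor CSF3 rose (2.66 ± 0.302).

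The unfolded protein response had 12 of 29 higher and 3 lower at 16 h (14 and 3 list-wise), with XBP1 (1.43 ± 0.174), PDIA4 (1.27 ± 0.17) and the stress factor DDIT3 (1.49 ± 0.209). Its median was 0.56 (camera adjusted p = 0.00119). Glycolysis and hypoxia genes had 9 of 26 higher and 1 lower (10 and 1 list-wise), with VEGFA higher (2.38 ± 0.195) and the oxygen sensor EGLN3 lower (-2.31 ± 0.245). Their median was 0.34 (camera adjusted p = 0.00993). Mitosis genes had 8 of 43 higher and 0 lower by both adjustments. They had a median of 0.40 (camera adjusted p = 0.0164). Oxidative phosphorylation had 2 of 46 lower and 1 higher (0 and 0 list-wise), with a median of -0.29 (camera adjusted p = 0.00993). The Notch, Wnt and TGF-beta list had 7 of 29 lower and 5 higher (8 and 5 list-wise), with IGFBP5 lower (-3.12 ± 0.44) and ID1, an inhibitor of myogenic factors, higher (2.73 ± 0.43). Its median was -0.39 (camera adjusted p = 0.034).

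Single libraries decided several of these list results at 16 h. Without control 16 h replicate 2 the mitosis (adjusted p = 0.149) and oxidative phosphorylation (0.0564) calls ended. The Notch, Wnt and TGF-beta call ended without lncFAM 16 h replicate 3 (0.103), with limma-voom weights (0.0501) and with the length and GC trend removed (0.0575). It also ended with 2 replicates per group (0.104) or with the length slope as a covariate (0.0942). That covariate ended the mitosis (0.101) and oxidative phosphorylation (0.122) calls as well. The 8 mitosis genes higher were 1 and 3 without control 16 h replicates 2 and 3, and 4, 3 and 5 without lncFAM 16 h replicates 1, 2 and 3. The 11 ribosomal genes lower were 7, 7 and 6 without control 16 h replicates 1, 2 and 3, and 6 and 6 without lncFAM 16 h replicates 1 and 3.

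The lists that missed camera at 16 h are given by members only. Myogenic transcription factors had 7 of 26 higher, such as MYF5, a factor of early myoblasts (1.06 ± 0.222), and 3 lower, such as the smooth muscle co-activator MYOCD (-3.68 ± 0.465). Adjusted over the list alone they had 7 and 7. Neuromuscular junction genes had 4 of 16 higher and 6 lower (4 and 7 list-wise), with agrin AGRN higher (2.26 ± 0.324) and the fetal receptor subunit CHRNG lower (-1.53 ± 0.229). For p53 targets 8 of 30 were higher and 3 lower (9 and 4 list-wise), with the death receptor FAS higher (2.55 ± 0.367) and the cell cycle inhibitor CDKN1C lower (-2.33 ± 0.35). Extracellular matrix genes had 11 of 50 higher and 4 lower (12 and 6 list-wise), with basement membrane collagen COL4A1 higher (2.21 ± 0.222) and THBS2 lower (-3.19 ± 0.334). DNA replication had 3 of 48 higher and 1 lower (3 and 1 list-wise). Immediate early genes had 4 of 26 higher and 3 lower (4 and 4 list-wise). Markers of other cell types went both ways. Fibroblast markers had 3 of 19 higher and 4 lower (4 and 4 list-wise), and smooth muscle markers had 1 of 17 higher and 3 lower (1 and 5). Endothelial markers had 1 of 7 higher and 1 lower by both adjustments. Leukocyte markers had 2 of 10 higher and 1 lower (2 and 2 list-wise), and adipocyte markers had 1 of 11 higher and 3 lower by both adjustments. The lysosomal protein CD68, a macrophage marker, rose from 18.2 ± 3.2 to 498 ± 140 CPM (4.78 ± 0.277). Counts of 7 or fewer members often moved by a large factor when a library was left out. Myogenic factors higher, for instance, went from 7 to 3, 4 and 4 without control 16 h replicate 2 and lncFAM 16 h replicates 1 and 2. Median and camera differed in sign for the myogenic factor, smooth muscle, adipocyte and immediate early lists, and median and mean for the fibroblast and leukocyte lists.

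In all, 2405 genes were higher and 1867 lower at 16 h, of which 1838 and 1227 changed at least 2-fold. Without lncFAM 16 h replicate 1 the genes lower were 1169. Of the calls 56.3% were higher, against 52.6% with RLE and 51.4% with upper-quartile scaling.

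The same comparison at 48 h asks what differs later in differentiation. Interferon-stimulated genes were again the largest rises, with MX1 at 1710 ± 310 against 5.27 ± 1.8 CPM (8.34 ± 0.36) and OAS1 at 441 ± 42 against 1.67 ± 0.22 CPM (8.05 ± 0.316). IFI27 stood at 612 ± 95 against 0.872 ± 0.032 CPM (9.46 ± 0.385). Of the 43 tested members 42 rose and 0 fell by both adjustments, with a median of 5.26 (camera adjusted p = 3.09e-40; 0.0102 with estimated correlation). F13A1 fell from 2410 ± 85 to 49.5 ± 6 CPM (-5.61 ± 0.501) and AIF1L from 290 ± 54 to 9.02 ± 2.9 CPM (-5.01 ± 0.5). ARNT2, a partner of basic helix-loop-helix factors, fell from 233 ± 41 to 11 ± 2.5 CPM (-4.41 ± 0.296). DPYSL3, a cytoskeletal regulator, also fell (-3.82 ± 0.274).

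Sarcomere genes were lower at 48 h, with 32 of 71 lower and 5 higher (36 and 7 list-wise). Their median was -0.85 (camera adjusted p = 2.09e-05). MYH3 stood at 350 ± 130 against 2250 ± 760 CPM (-2.69 ± 0.597, adjusted p = 0.00502) and ANKRD1 at 389 ± 130 against 2550 ± 160 CPM (-2.71 ± 0.282). The thin-filament leiomodin LMOD2 stood at 0.925 ± 0.3 against 24.4 ± 6 CPM (-4.72 ± 0.464), while ANKRD2 rose (1.91 ± 0.233). Calcium-handling genes had 12 of 28 lower and 0 higher (12 and 1 list-wise), with a median of -0.82 (camera adjusted p = 9.67e-05). Sarcolipin SLN, an inhibitor of the calcium pump, fell from 20.0 ± 5 to 0.286 ± 0.059 CPM (-6.12 ± 0.35) and the junction protein JPH1 fell (-5.29 ± 0.545). Apart from the interferon-stimulated list, the 6 lists called at 48 h lost their calls with an estimated correlation (adjusted p between 0.514 and 0.835). By fry the mitosis list missed (adjusted p = 0.14) and the fusion (0.00993), p53 (0.0423) and unfolded protein response (0.000303) lists passed. Mitosis genes had 11 of 43 lower and 2 higher (14 and 2 list-wise), such as ANLN (-2.07 ± 0.44) and CDK1 (-1.30 ± 0.308). They had a median of -0.35 (camera adjusted p = 0.0122). Mitochondrially encoded genes had 5 of 13 lower and 0 higher (7 and 0 list-wise), with MT-CO3 at -1.76 ± 0.219. Their median was -0.59 (camera adjusted p = 0.00698).

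Markers of other cell types also passed camera at 48 h. Smooth muscle markers had 7 of 17 lower and 0 higher (8 and 0 list-wise), such as the actin ACTA2 (-2.28 ± 0.3) and TAGLN (-1.76 ± 0.229), both also made by differentiating muscle cells, and library medians of the groups overlapped. Their median was -0.59 (camera adjusted p = 0.0142). Leukocyte markers had 7 of 10 lower and 2 higher by both adjustments, with a median of -1.76 (camera adjusted p = 0.0153). LAPTM5 (-2.03 ± 0.195) and the integrin ITGAM (-3.67 ± 0.397) fell, while CD68 stood at 145 ± 22 against 4.25 ± 0.88 CPM (5.08 ± 0.282). Among the landmarks MYOD1 rose from 101 ± 25 to 208 ± 57 CPM (1.05 ± 0.245, adjusted p = 0.00679). MYOG (-0.29 ± 0.457, adjusted p = 0.682), MYH8 (-1.85 ± 0.747, 0.0869), CKM (-0.93 ± 0.675, 0.344) and MKI67 (-0.63 ± 0.38, 0.25) were not called. MYH8 was called without lncFAM 16 h replicate 3 (adjusted p = 0.0246) or lncFAM 48 h replicate 2 (0.00936), by limma-voom (0.0374), with upper-quartile scaling (0.0416) and with a replicate block (0.0168). It was also called with only the groups compared (0.0499), with 2 replicates per group (0.00403) and without a filter (8.08e-10). CKM was called with 2 replicates per group (0.0218) and without a filter (0.00429), and MKI67 without lncFAM 48 h replicate 2 (0.0349). PAX7 stood at 0.0565 ± 0.051 against 0.267 ± 0.1 CPM and was not called (-2.25 ± 0.766, adjusted p = 0.0504). It was called without control 16 h replicate 2 (adjusted p = 0.0299), control 48 h replicate 1 (0.0447) or lncFAM 48 h replicate 2 (0.015), by DESeq2 (0.0241) and by limma-voom (0.0183). RLE (0.0375) and upper-quartile scaling (0.0371), no filter (0.0191), only the groups compared (0.0412), protein-coding genes only (0.0308) and removal of the length and GC trend (0.033) also gave a call for PAX7. The MYOG effects at the 2 times were not shown to differ (log2 1.41, SE 0.65, edgeR adjusted p = 0.281), though without a filter on low counts that test passed (adjusted p = 0.0171). The MYOD1 call ended without control 48 h replicate 1 (adjusted p = 0.0697) or lncFAM 48 h replicate 3 (0.0591).

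Several list results at 48 h rested on single libraries. Without lncFAM 48 h replicate 2 the mitochondrially encoded (adjusted p = 0.0687), leukocyte (0.0687) and smooth muscle (0.0719) calls ended. The mitosis call ended with 2 replicates per group (0.078) and the mitochondrially encoded call with the length and GC trend removed (0.0683). The 32 sarcomere genes lower were 20 and 19 without control 48 h replicate 2 and lncFAM 48 h replicate 1. The 11 mitosis genes lower were 5 and 5 without control 48 h replicates 1 and 2, and 5 and 18 without lncFAM 48 h replicates 1 and 2. The 7 smooth muscle markers lower were 4 without either control 48 h replicate 2 or lncFAM 48 h replicate 1, and the 5 mitochondrially encoded genes lower were 3 without lncFAM 48 h replicate 1.

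Lists that missed camera at 48 h are given by their called members. Myogenic transcription factors had 6 of 26 higher and 4 lower (7 and 5 list-wise), with PAX3 (1.94 ± 0.304) and MYF5 (1.07 ± 0.222) higher. Fusion and membrane genes had 6 of 30 higher and 9 lower (6 and 13 list-wise). Neuromuscular junction genes had 3 of 16 higher and 4 lower by both adjustments. Muscle metabolism had 3 of 26 higher and 8 lower (3 and 9 list-wise). Extracellular matrix genes had 18 of 50 higher and 8 lower (21 and 8 list-wise), with TGFBI higher (2.30 ± 0.194) and THBS2 lower (-3.29 ± 0.34). For p53 targets 11 of 30 were higher and 6 lower (12 and 6 list-wise). For the unfolded protein response 11 of 29 were higher and 2 lower (12 and 3 list-wise). Inflammatory genes had 5 of 21 higher and 5 lower (5 and 6 list-wise). DNA replication had 4 of 48 higher and 7 lower, and glycolysis and hypoxia 5 of 26 higher and 4 lower, both lists with equal counts by either adjustment. The Notch, Wnt and TGF-beta list had 5 of 29 higher and 6 lower (6 and 7 list-wise). Cholesterol synthesis had 3 of 25 higher and 0 lower (1 and 0 list-wise).

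Small counts were found at 48 h for hnRNP genes, 1 of 31 higher and 3 lower, and ribosomal proteins, 2 of 41 each way (1 each list-wise). Oxidative phosphorylation had 3 of 46 higher and 1 lower (0 and 0 list-wise), and immediate early genes had 2 of 26 higher and 3 lower (4 and 4). Fibroblast markers had 3 of 19 higher and 4 lower (4 and 5 list-wise). Adipocyte markers had 2 of 11 higher and 3 lower (3 and 3 list-wise), and endothelial markers 0 of 7 higher and 1 lower (0 and 0). Without lncFAM 48 h replicate 2 the fusion genes lower were 14. Muscle metabolism genes lower were 5 without control 48 h replicate 2 or 3, and matrix genes lower 5 without lncFAM 48 h replicate 1. Unfolded protein response genes higher were 6, 7 and 6 without control 48 h replicates 1 and 2 and lncFAM 48 h replicate 1. Median and camera differed in sign for the endothelial, adipocyte and glycolysis lists.

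At 48 h 3363 genes were higher and 2421 lower, of which 2118 and 1910 changed at least 2-fold. The excess of higher calls (58.1%) rests on the scaling, with 50.0% by RLE and 54.6% by upper quartile. The genes higher were 2012, 2160 and 1944 without control 48 h replicate 1, control 48 h replicate 2 and lncFAM 48 h replicate 1. The genes lower were 1596 and 4398 without control 48 h replicate 2 and lncFAM 48 h replicate 2. The siRNA effects at the 2 times rest on separate libraries. Both called 1550 genes higher (349 if the calls were independent) and 866 lower (195), while 45 rose at 16 h and fell at 48 h (251) and 34 did the opposite (271).

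**Figure D3:**
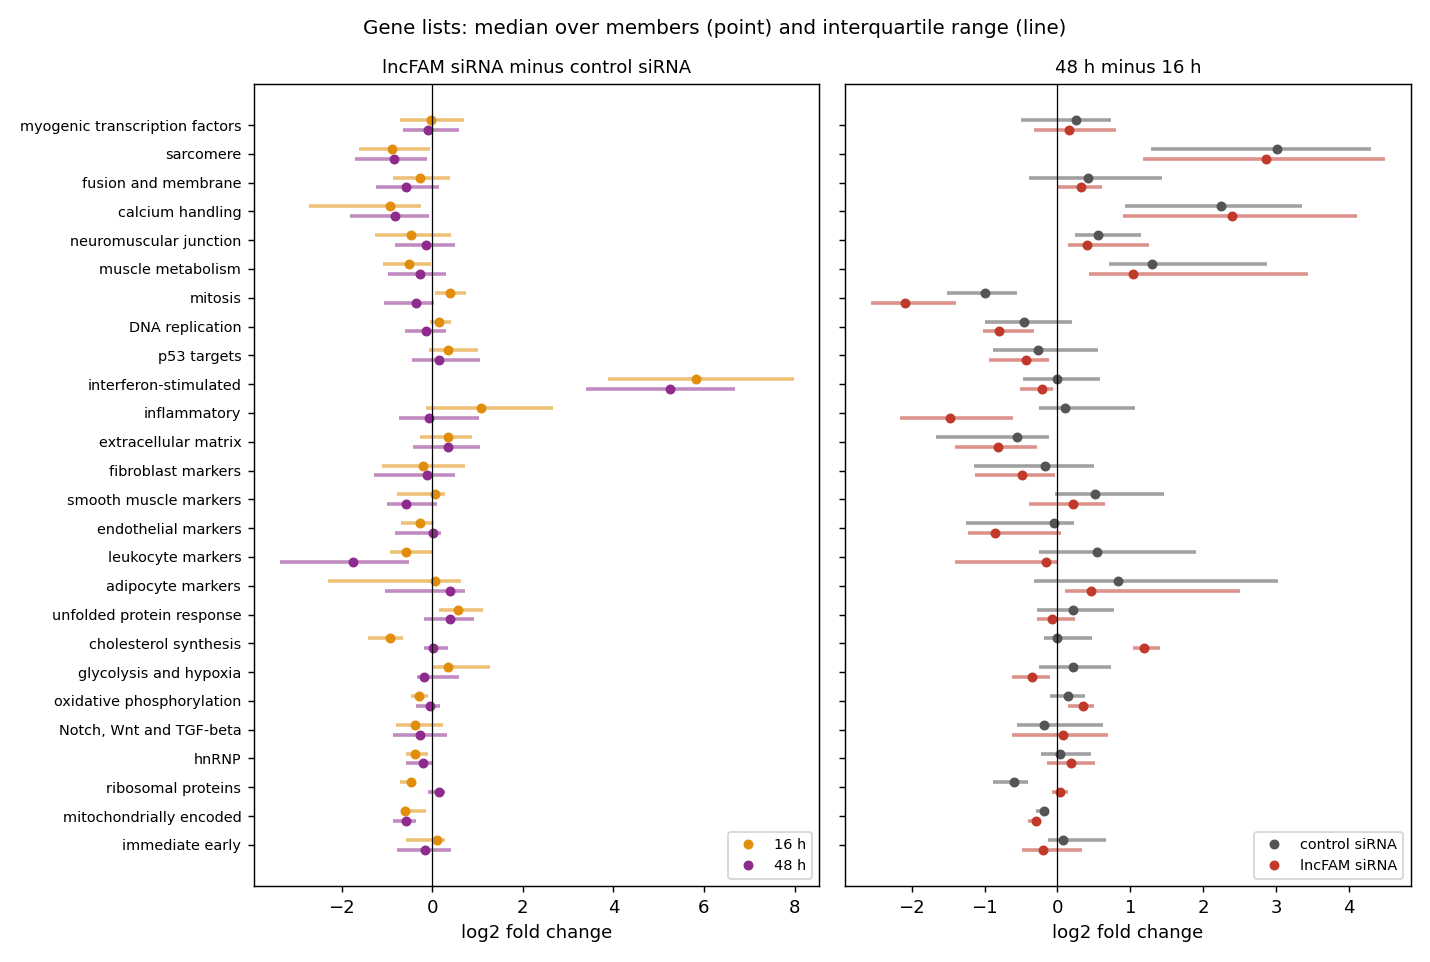
Median log2 fold change (point) and interquartile range (line) of the 26 gene lists, for the siRNA effect at 16 h and 48 h on the left and for the time effect with control and with lncFAM siRNA on the right, from 3 libraries per group. The interferon-stimulated list stands at 5.83 and 5.26 on the left, and the sarcomere list at 3.01 and 2.86 on the right.

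The time effect with control siRNA shows how the cultures changed from 16 h to 48 h. Sarcomere genes rose, 57 of 71 higher and 0 lower (62 and 2 list-wise), with a median of 3.01 (camera adjusted p = 1.83e-28). Skeletal actin ACTA1 went from 7.46 ± 5.3 to 438 ± 130 CPM (5.88 ± 0.78) and MYH3 from 45.3 ± 21 to 2250 ± 760 CPM (5.64 ± 0.685). Calcium-handling genes had 22 of 28 higher and 0 lower (26 and 0 list-wise), with calsequestrin CASQ2 going from 3.27 ± 1.5 to 258 ± 24 CPM (6.30 ± 0.671). Their median was 2.25 (camera adjusted p = 6.3e-15). Muscle metabolism had 18 of 26 higher and 1 lower (20 and 1 list-wise), with creatine kinase CKM at 6.10 ± 0.838. Its median was 1.29 (camera adjusted p = 1.12e-08). Neuromuscular junction genes had 4 of 16 higher and 0 lower (5 and 0 list-wise), with a median of 0.56 (camera adjusted p = 0.0048). MYBPC2 (4.15 ± 0.601, adjusted p = 0.000382), MYH8 (6.87 ± 0.938, 0.000248) and lncFAM (2.15 ± 0.435, 0.00379) rose. PAX7 rose from 0.0368 ± 0.034 to 0.267 ± 0.1 CPM (2.74 ± 0.785, adjusted p = 0.0293). Its call ended without control 16 h replicates 1 (adjusted p = 0.0728), 2 (0.0814) or 3 (0.0559), control 48 h replicates 2 (0.0958) or 3 (0.0746), and with the length slope as a covariate (0.0835). HNRNPL (-0.42 ± 0.172, adjusted p = 0.102), MYOG (0.37 ± 0.458, 0.586), MYOD1 (-0.71 ± 0.243, 0.0529) and MKI67 (-0.78 ± 0.375, 0.153) were not called. MYOD1 was called without control 16 h replicate 1 (adjusted p = 0.0495), control 48 h replicate 3 (0.0252) or lncFAM 48 h replicates 2 (0.0311) and 3 (0.038). DESeq2 (0.0363), limma-voom (0.0452), upper-quartile scaling (0.0402), a replicate block (0.0327), only the groups compared (0.0442) and a CPM of at least 1 in at least 3 libraries (0.0493) also called MYOD1. So did protein-coding genes only (0.0492), the thinned library (0.0497), 2 replicates per group (0.0147) and the length and GC trend removed (0.00388). MKI67 was called with that trend removed (0.0358) and with the length slope as a covariate (0.00132).

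Other lists fell over time with control siRNA. All 8 called by camera lost their calls with an estimated correlation (adjusted p between 0.197 and 0.446). Mitosis had 21 of 43 lower and 1 higher (29 and 2 list-wise), with CCNB2 (-2.80 ± 0.231) lower. Its median was -0.99 (camera adjusted p = 2.96e-11). DNA replication had 17 of 48 lower and 3 higher (18 and 4 list-wise), with a median of -0.46 (camera adjusted p = 0.000798). Extracellular matrix genes had 20 of 50 lower and 5 higher (22 and 6 list-wise), with a median of -0.55 (camera adjusted p = 5.14e-07). The protease MMP2 went from 563 ± 63 to 76.4 ± 10 CPM (-2.88 ± 0.216). Ribosomal protein genes had 15 of 41 lower and 0 higher (19 and 0 list-wise), with a median of -0.59 (camera adjusted p = 1.97e-08). The 17 replication genes lower were 9, 11 and 10 without control 16 h replicate 3 and control 48 h replicates 1 and 2. The 15 ribosomal genes lower were 4 without control 16 h replicate 2, and 3, 3 and 33 without control 48 h replicates 1, 2 and 3. With the length slope as a covariate they were 4, with a median of -0.18.

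Among the lists that missed camera over time with control siRNA, myogenic factors had 5 of 26 higher and 5 lower (7 and 6 list-wise), with SMYD1 higher (2.49 ± 0.307). Fusion and membrane genes had 12 of 30 higher and 5 lower (15 and 5 list-wise), with MYMK (2.58 ± 0.307) higher. For p53 targets 1 of 30 was higher and 11 lower (2 and 12 list-wise). Interferon-stimulated genes had 5 of 43 higher and 6 lower (6 and 6 list-wise). Inflammatory genes had 2 of 21 higher and 3 lower by both adjustments. Fibroblast markers had 2 of 19 higher and 5 lower by both adjustments. Smooth muscle markers had 7 of 17 higher and 2 lower by both adjustments, with ACTA2 at 1.5 ± 0.292, and endothelial markers had 0 of 7 higher and 2 lower (0 and 3). Leukocyte markers had 3 of 10 higher and 1 lower, with ITGAM at 2.03 ± 0.353 and CD68 at -2.09 ± 0.248, and adipocyte markers 4 of 11 higher and 0 lower, by both adjustments. The unfolded protein response had 6 of 29 higher and 5 lower (6 and 6 list-wise), and glycolysis and hypoxia had 6 of 26 higher and 1 lower (7 and 2). Oxidative phosphorylation had 4 of 46 higher and 0 lower (1 and 0 list-wise), and the Notch, Wnt and TGF-beta list had 3 of 29 higher and 5 lower (3 and 6). The hnRNP genes had 2 of 31 each way (1 each list-wise) and immediate early genes 3 of 26 higher and 3 lower (5 and 4). Of 25 cholesterol genes edgeR called 0, with 4 at an unadjusted p under 0.05 and 1 called by DESeq2 and 1 by limma-voom. Of 13 mitochondrially encoded genes all 3 tools called 0, with 0 at an unadjusted p under 0.05. The 12 fusion genes higher were 7, 6 and 7 without control 16 h replicates 2 and 3 and control 48 h replicate 2. Median and test differed in sign for the inflammatory and hnRNP lists. By fry the fusion (adjusted p = 0.000645), p53 (0.00263), fibroblast (0.00803), smooth muscle (0.00146), adipocyte (0.00582) and unfolded protein response (0.0446) lists passed.

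With control siRNA 2357 genes rose and 2340 fell over time, of which 1852 and 1342 changed at least 2-fold. Of the calls 50.2% were higher, against 50.3% by RLE and 41.7% by upper quartile. The genes higher were 1571, 1334 and 1432 without control 16 h replicate 2, control 16 h replicate 3 and control 48 h replicate 2. The genes lower were 1555, 1324, 1254 and 1166 without control 16 h replicates 2 and 3 and control 48 h replicates 1 and 2.

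With lncFAM siRNA 5 muscle lists rose by camera from 16 h to 48 h, while myogenic factors missed. Of the 18 lists called in this contrast 16, these 5 included, lost their calls with an estimated correlation (adjusted p between 0.0793 and 0.634). Sarcomere genes had 55 of 71 higher and 0 lower (60 and 0 list-wise), with a median of 2.86 (camera adjusted p = 3.92e-38). Calcium-handling genes had 21 of 28 higher and 0 lower (21 and 2 list-wise). Their median was 2.4, or 2.35 with a member of at most 3 counts in each group left out (camera adjusted p = 1.29e-15). CASQ2 went from 0.535 ± 0.46 to 66.0 ± 17 CPM (6.93 ± 0.706), MYH3 from 7.71 ± 5.4 to 350 ± 130 CPM (5.50 ± 0.682) and MYBPC2 from 1.85 ± 1.4 to 68.4 ± 26 CPM (5.21 ± 0.638). Muscle metabolism had 12 of 26 higher and 0 lower (16 and 0 list-wise). The median of that list was 1.03, or 1.02 with a member of so few counts left out (camera adjusted p = 1.59e-10). Fusion and membrane genes had 7 of 30 higher and 1 lower (8 and 1 list-wise), with a median of 0.32 (camera adjusted p = 0.00922). Neuromuscular junction genes had 6 of 16 higher and 0 lower (7 and 0 list-wise), with a median of 0.41 (camera adjusted p = 0.000184). MYOG (1.78 ± 0.471, adjusted p = 0.0267), MYH8 (6.51 ± 0.928, 0.000518), CKM (6.53 ± 0.86, 0.000296) and lncFAM (1.81 ± 0.493, 0.0312) rose, and MKI67 fell (-2.29 ± 0.391, 0.00187). HNRNPL (0.57 ± 0.172, adjusted p = 0.0504) and MYOD1 (-0.19 ± 0.242, 0.728) were not called. HNRNPL was called without lncFAM 48 h replicate 2 (adjusted p = 0.04), by limma-voom (0.0432), with control 48 h replicate 3 thinned (0.0495), with the length and GC trend removed (0.015) and with the length slope as a covariate (0.00821). PAX7, with no counts at 16 h and 0.0565 ± 0.051 CPM at 48 h, was not called (adjusted p = 0.0783), though it was by DESeq2 (0.0248) and without a filter (0.0205). The lncFAM call ended without lncFAM 16 h replicate 2 (adjusted p = 0.0729) or 3 (0.0513) and with only the groups compared (0.112). The MYOG call ended without lncFAM 16 h replicate 1 (0.0766) or lncFAM 48 h replicate 3 (0.06) and with only the groups compared (0.0874).

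Mitosis genes fell over time with lncFAM siRNA, 36 of 43 lower and 0 higher (42 and 0 list-wise), with CDC20 (-2.93 ± 0.247) lower. Their median was -2.09 (camera adjusted p = 4.77e-35; 0.0319 with estimated correlation). Inflammatory genes had 11 of 21 lower and 0 higher (15 and 0 list-wise), such as the adhesion molecule ICAM1 (-3.33 ± 0.588). They had a median of -1.47 (camera adjusted p = 1.69e-10; 0.0314 with estimated correlation). Cholesterol synthesis rose, 19 of 25 higher and 0 lower (22 and 0 list-wise). Its median was 1.19 (camera adjusted p = 2.66e-13). DNA replication had 17 of 48 lower and 2 higher (27 and 2 list-wise), with a median of -0.80 (camera adjusted p = 9.23e-11). Extracellular matrix genes had 23 of 50 lower and 3 higher (30 and 4 list-wise), with a median of -0.82 (camera adjusted p = 2.49e-11). The p53 targets had 9 of 30 lower and 1 higher by both adjustments, with a median of -0.43 (camera adjusted p = 0.000958). Interferon-stimulated genes had 4 of 43 lower and 0 higher by both adjustments. Their list had a median of -0.21 (camera adjusted p = 0.00207). The 17 replication genes lower were 11 without lncFAM 16 h replicate 3, and the 9 p53 targets lower 3 and 5 without lncFAM 16 h replicate 3 and lncFAM 48 h replicate 1. The 19 cholesterol genes higher were 12 without lncFAM 48 h replicate 1, and the 4 interferon-stimulated genes lower were 11 without lncFAM 48 h replicate 2.

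Further lists passed camera over time with lncFAM siRNA. By fry the interferon-stimulated (adjusted p = 0.0921), oxidative phosphorylation (0.0631) and mitochondrially encoded (0.255) lists missed and endothelial markers passed (0.00776). Library medians of the 2 times overlapped for the fusion, interferon-stimulated, adipocyte and mitochondrially encoded lists. Oxidative phosphorylation had 4 of 46 higher and 0 lower (3 and 0 list-wise), with a median of 0.35 (camera adjusted p = 0.000442). Adipocyte markers had 3 of 11 higher and 0 lower by both adjustments. Their median was 0.46 (camera adjusted p = 0.00617). Fibroblast markers had 4 of 19 lower and 1 higher (5 and 1 list-wise), with a median of -0.48 (camera adjusted p = 0.0251). Leukocyte markers had 3 of 10 lower and 0 higher by both adjustments, with a median of -0.16 (camera adjusted p = 0.0251). Glycolysis and hypoxia had 3 of 26 lower and 2 higher (6 and 3 list-wise), with a median of -0.35 (camera adjusted p = 0.0105). Of 13 mitochondrially encoded genes edgeR, DESeq2 and limma-voom called 0, with 0 at an unadjusted p under 0.05. The median of these was -0.29 (camera adjusted p = 0.0318). The fibroblast call ended without lncFAM 16 h replicate 1 (adjusted p = 0.0587), lncFAM 16 h replicate 2 (0.0664) or lncFAM 48 h replicate 2 (0.0787), and the glycolysis call without lncFAM 48 h replicate 2 (0.184). The leukocyte call ended without lncFAM 16 h replicate 3 (0.133), lncFAM 48 h replicate 2 (0.0871) or lncFAM 48 h replicate 3 (0.0571) and with 2 replicates per group (0.24). The mitochondrially encoded call ended without lncFAM 16 h replicate 3 (0.21), lncFAM 48 h replicate 1 (0.224) or lncFAM 48 h replicate 2 (0.243) and with the length and GC trend removed (0.0728).

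Lists that missed camera over time with lncFAM siRNA were myogenic factors, 6 of 26 higher and 3 lower (9 and 4 list-wise), and smooth muscle, 2 of 17 each way (5 and 2). Endothelial markers had 0 of 7 higher and 1 lower, and the unfolded protein response 2 of 29 higher and 1 lower. The Notch, Wnt and TGF-beta list had 6 of 29 each way and hnRNP genes had 3 of 31 higher and 0 lower (4 and 0 list-wise). Of 41 ribosomal protein genes 0 were called by edgeR, DESeq2 or limma-voom, with 2 at an unadjusted p under 0.05. Immediate early genes had 2 of 26 higher and 1 lower (3 and 1 list-wise). Median and test differed in sign for the Notch, Wnt and TGF-beta list.

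With lncFAM siRNA 1336 genes rose and 1065 fell over time, of which 1062 and 838 changed at least 2-fold. Of the calls 55.6% were higher, against 51.0% by RLE and by upper quartile. The genes lower were 658 without lncFAM 16 h replicate 3 and 1953 without lncFAM 48 h replicate 2.

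Whether the siRNA effect itself changed with time was tested by the interaction. It called 261 genes with a more positive and 290 with a more negative siRNA effect at 48 h than at 16 h (47.4% more positive, 40.1% by RLE and 46.7% by upper quartile). PPL, a plakin of cell junctions (3.69 ± 0.521), was lower than control at 16 h, at 4.62 ± 0.58 against 52.1 ± 22 CPM, and stood at 19.6 ± 8.8 against 17.2 ± 6 CPM at 48 h. RAB11FIP1, a membrane recycling factor (3.06 ± 0.386), and STEAP3, an iron reductase (2.85 ± 0.309), also had more positive effects at 48 h. PMAIP1, a pro-apoptotic protein (-4.36 ± 0.559), stood at 22.2 ± 3.6 against 1.23 ± 0.33 CPM at 16 h and 10.3 ± 6.6 against 11.6 ± 1.9 CPM at 48 h. The decoy receptor TNFRSF11B (-4.16 ± 0.593) and the apoptosis inhibitor BIRC3 (-3.78 ± 0.642) also had more negative effects at 48 h. The genes more positive were 170, 112 and 103 without control 16 h replicates 1, 2 and 3, and 86 and 137 without lncFAM 16 h replicates 1 and 2. They were 81 and 64 without control 48 h replicates 1 and 2, and 78, 877 and 136 without lncFAM 48 h replicates 1, 2 and 3. Those more negative were 164 without control 16 h replicate 3, 155 without lncFAM 16 h replicate 1 and 125 without control 48 h replicate 2. Without lncFAM 48 h replicates 1 and 2 they were 191 and 2326.

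By lists, cholesterol synthesis had a more positive siRNA effect at 48 h, with 6 of 25 genes called higher and 0 lower (18 and 0 list-wise). Its median was 1.22 (camera adjusted p = 8.89e-09). Ribosomal proteins had 1 of 41 higher and 0 lower (4 and 0 list-wise), with a median of 0.70, or 0.23 with the length slope as a covariate (camera adjusted p = 8.89e-09). Inflammatory genes had a more negative effect, 2 of 21 lower and 0 higher (8 and 1 list-wise), with a median of -1.43 (camera adjusted p = 3.42e-06). Mitosis had 2 of 43 lower and 0 higher (6 and 0 list-wise), with a median of -0.90 (camera adjusted p = 2.24e-07). Leukocyte markers had 2 of 10 lower and 0 higher (4 and 0 list-wise), with a median of -0.87 (camera adjusted p = 0.0031). Glycolysis and hypoxia had 3 of 26 lower and 0 higher (7 and 1 list-wise). The median of that list was -0.33 (camera adjusted p = 0.0051). The interferon-stimulated list had 2 of 43 lower and 0 higher (4 and 1 list-wise), with a median of -0.39 (camera adjusted p = 0.0331). Of 17 smooth muscle markers edgeR called 0, DESeq2 1 and limma-voom 1, with 5 at an unadjusted p under 0.05 (4 lower and 0 higher adjusted over the list alone). The median of these was -0.58 (camera adjusted p = 0.0452).

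The 8 list calls of the interaction ended with an estimated correlation (adjusted p between 0.149 and 0.841). By fry the mitosis (adjusted p = 0.0537), interferon-stimulated (0.316) and ribosomal (0.116) lists missed. The glycolysis call ended without control 48 h replicate 3 (adjusted p = 0.0707) or lncFAM 48 h replicate 2 (0.224) and the leukocyte call without lncFAM 48 h replicate 2 (0.0559). The interferon call ended without control 16 h replicate 3 (adjusted p = 0.162), control 48 h replicates 1 (0.0627) and 2 (0.0865) and lncFAM 16 h replicates 1 (0.0582) and 2 (0.088). It also ended without lncFAM 48 h replicates 2 (0.0581) and 3 (0.101), with protein-coding genes only (0.0822) and with the length and GC trend removed (0.0517). With the length slope as a covariate its direction turned, with a median of 0.25 (adjusted p = 0.789). The smooth muscle call ended without control 16 h replicates 1 (adjusted p = 0.1) and 3 (0.0993), control 48 h replicates 1 (0.125) and 3 (0.0929) and lncFAM 16 h replicates 1 (0.0582) and 3 (0.0712). It also ended without lncFAM 48 h replicates 1 (0.0767) and 2 (0.301), with RLE scaling (0.0557) and with protein-coding genes only (0.103). The 6 cholesterol genes were 2 and 3 without control 16 h replicate 2 and lncFAM 16 h replicate 1. They were 2 and 1 without control 48 h replicates 1 and 2, and 2 and 17 without lncFAM 48 h replicates 1 and 2.

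Camera did not call the other lists in the interaction, given here with members higher and lower. The sarcomere (0 and 3 of 71), calcium handling (2 and 0 of 28), fusion and membrane (1 and 0 of 30), neuromuscular junction (2 and 1 of 16) and muscle metabolism (2 and 1 of 26) lists were among them. So were the myogenic factor (0 and 1 of 26), matrix (3 and 5 of 50), fibroblast (2 and 0 of 19), unfolded protein response (1 and 1 of 29), Notch, Wnt and TGF-beta (3 and 1 of 29), hnRNP (1 and 0 of 31) and immediate early (0 and 2 of 26) lists. In the other lists edgeR and limma-voom called 0. DESeq2 called 3 of 48 DNA replication genes (9 at an unadjusted p under 0.05 in edgeR) and 3 of 30 p53 targets (8). It called 0 of 7 endothelial (1), 11 adipocyte (2), 46 oxidative phosphorylation (4) and 13 mitochondrially encoded (0) genes. Median and test differed in sign for the sarcomere, calcium handling and endothelial lists, and the mean differed from these for the fusion and matrix lists.

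The time and siRNA effects were set against each other to ask whether silencing moved genes against the course of differentiation. At 48 h 1086 of the genes that rose over time with control siRNA were lower with lncFAM siRNA (46.1% of them, 246 if independent). Of those that fell over time 1019 were higher (43.5%, 339 if independent). The 2 effects went the same way in 71 genes higher (342 if independent) and 69 lower (244). Both contrasts use the control 48 h libraries, which by itself gives a negative relation. Pearson's r across genes was -0.52, against -0.49 in 20 simulations of unchanged groups, and the covariance -0.63 against -0.078 (difference -0.56). These held no changed genes, so their 0 calls in both contrasts give no chance level. At 16 h, where shared controls push the other way, 280 genes rose in both contrasts (244 if independent) and 325 fell in both (188). A further 395 rose over time and were lower with lncFAM siRNA (190 if independent) and 366 fell over time and were higher (243). Pearson's r was 0.01 against a simulated 0.50, and the covariance was 0.01 against a simulated 0.081, a difference of -0.07. The covariance lay above the simulated one without control 16 h replicates 1 (0.23) and 2 (0.109) and level with it without lncFAM 16 h replicate 3 (0.082). It was below 0 without lncFAM 16 h replicate 2 (-0.033) and with a CPM of at least 1 in at least 3 libraries (-0.048). The simulations held all 12 libraries. Genes are not independent replicates, and 3 control libraries per time cannot be split between the 2 contrasts with at least 2 in each.

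Single libraries moved these overlaps. At 48 h the 1086 were 612 and 2004 without control 48 h replicate 2 and lncFAM 48 h replicate 2. The 1019 were 664 and 631 without control 16 h replicates 2 and 3, 470 without either control 48 h replicate 1 or 2 and 583 without lncFAM 48 h replicate 1. The 71 were 46 and 42 without control 16 h replicates 2 and 3, 29, 33 and 42 without control 48 h replicates 1, 2 and 3 and 41 without lncFAM 48 h replicate 1. The 69 were 35 without control 16 h replicate 3, 30 and 26 without control 48 h replicates 1 and 2 and 43 without lncFAM 48 h replicate 1. At 16 h the 280 were 162 and 141 without control 16 h replicates 2 and 3, 163 without control 48 h replicate 2 and 432 and 433 without lncFAM 48 h replicates 2 and 3. The 395 were 251, 248 and 258 without control 16 h replicates 1, 2 and 3. The 366 were 233, 202 and 186 without control 16 h replicates 1, 2 and 3 and 214 and 208 without control 48 h replicates 1 and 2. The 325 were 215 and 120 without control 16 h replicates 2 and 3, 166 and 197 without lncFAM 16 h replicates 1 and 2 and 170 and 149 without control 48 h replicates 1 and 2.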

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

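Among the tests below, those of leukocytes, of an innate response to the transfected RNA, of a lower share of muscle cells, of genes that rise with time and of balanced relabellings were chosen only after the result was seen, as were the fits with protein-coding genes only, a thinned library, the length and GC trend removed, and the length slope as a covariate.

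Interferon-stimulated genes were higher in the lncFAM siRNA libraries, 43 of 43 at 16 h and 42 of 43 at 48 h. Leukocytes in the culture are argued against: the median of the 10 leukocyte markers, of which 0 stand in another list, was -0.59 at 16 h and -1.76 at 48 h. Of the 2 most abundant markers, LAPTM5 went from 9.41 to 5.94 CPM at 16 h while CD68, also made by other cells, went from 18.2 to 498 CPM. CD14 rose too (1.72 ± 0.32). Library scaling is argued against, since at least 42 members were called higher under RLE, upper quartile and protein-coding genes only at both times. With 1 lncFAM siRNA arm, an innate response to the transfected RNA cannot be told apart from loss of lncFAM. Either may underlie the rise.

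Sarcomere genes were lower with lncFAM siRNA at 48 h, with a median of -0.85. A transcript length or GC trend between libraries is argued against as the whole cause: with the trend removed the median was -0.96, 112.9% of the uncorrected value (camera adjusted p = 1.36e-05), though the uncorrected list lost its call with an estimated correlation (adjusted p = 0.835). The depth of control 48 h replicate 3 is argued against too, since the higher of the medians with that library thinned or left out was -0.78. A lower share of muscle cells cannot be told apart from an effect within them: of the fibroblast, endothelial and adipocyte lists, whose members went both ways, 0 had an interquartile range below 0, and the leukocyte list, whose fall speaks against it (median -1.76, and -1.89 to -1.6 without each library), stood at a median log2 CPM of only 0.26 to 0.32 with control siRNA at 48 h. A slower or weaker differentiation after loss of lncFAM may account for the fall and stays open. With 1 arm, the overlap with the time effect at 48 h cannot tell it from another siRNA effect.

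MYBPC2, SPIB and lncFAM, neighbours on chromosome 19, were all lower with lncFAM siRNA. Reads shared among these 3 are argued against, as they share 0 exon bases. SPIB shares 839 with ENSG00000142539 and lncFAM 626 with EMC10, and both pairs stay open. A general loss of genes that rise with time cannot be told apart from an effect on MYBPC2 alone. Its siRNA effect was ranked among 200 genes with the closest time effect, matched on separate controls. It lay at percentiles 54.5 to 65.5 at 48 h and 2.5 to 8 at 16 h (6 control divisions). Such a loss is argued against for SPIB, which fell by -4.43 at 16 h and -3.20 at 48 h. Its time effect was 0.26 ± 0.352 with control siRNA (adjusted p = 0.621) and 1.49 ± 0.404 with lncFAM siRNA (0.0306). A local effect of lncFAM on this region could apply and is a hypothesis that was not tested.

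The siRNA effect differed between 16 h and 48 h, by edgeR's test of that difference, in 261 genes that were more positive and 290 that were more negative at 48 h. The log2 differences were 3.69 for PPL, 3.06 for RAB11FIP1, 3.02 for IGFBPL1, 2.85 for STEAP3 and 2.74 for IGFBP5. The IGFBP5 call ended without control 16 h replicate 3 (adjusted p = 0.0634), lncFAM 16 h replicate 1 (0.0543) or control 48 h replicate 2 (0.0872). The log2 differences were -4.36 for PMAIP1, -4.16 for TNFRSF11B, -3.78 for BIRC3, -3.36 for LOXL4 and -3.26 for DPYSL3. By camera, lists with a difference had medians of -0.90 for mitosis, -0.39 for interferon-stimulated genes, -1.43 for inflammatory genes and -0.58 for smooth muscle markers. Further medians were -0.87 for leukocyte markers, 1.22 for cholesterol synthesis, -0.33 for glycolysis and hypoxia and 0.70 for ribosomal proteins. With the length slope as a covariate the interferon-stimulated list turned to a median of 0.25 (adjusted p = 0.789). Each of these 8 list calls was lost with an estimated correlation (adjusted p between 0.149 and 0.841).

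Other splits of the same libraries were fitted to see how often as many genes are called. The 6 libraries of a pairwise comparison make 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each comparison. The real split called 4272 genes for the siRNA effect at 16 h, against at most 0 in another split, and 5784 at 48 h against 419. Over time it called 4697 genes with control siRNA against 0 and 2401 with lncFAM siRNA against 0. For the interaction 6 of 100 drawn relabellings, the real one included, called at least the real 551 genes. Of the 5 others 4 exchanged unequal numbers of libraries at the 2 times, which puts the siRNA effect itself into the difference. The highest, 7283, exchanged all siRNA labels at 48 h and so tested the sum of the siRNA effects, the structure of the samples that it points to. Of the 82 relabellings that exchange equal numbers at both times, 2 called at least 551, the real one and 1 with 1580, but their groups mix the siRNAs, which adds to the spread within groups. Neither share therefore shows whether chance can be excluded.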

How the results depend on the processing

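Of the settings compared here, 5 were tests chosen only after the data were seen, namely protein-coding genes only, the thinned library, 2 replicates per group, the length and GC trend removed, and the length slope as a covariate. Of 508 gene results that passed their test, 403 kept direction and call in every comparison run. Over 12621 comparisons 11967 kept both, 654 lost the call and 0 changed direction. Of 56 list results that passed camera, 4 kept their call throughout. Over 1176 comparisons 1072 kept it, 103 lost it and 1 reversed. That was the interferon-stimulated list in the interaction with the length slope as a covariate (adjusted p = 0.789). Results that had not passed are less settled. Of 2885 comparisons over 119 gene results 355 gained a call and 27 changed direction. Of 1554 over 74 list results 41 gained a call and 128 changed direction, so these lists are described by their called members only. Unless the setting itself tests fewer genes or libraries or asks for a lower p or a larger fold, the cause was not tested.

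The filter and tool settings moved the following. At an adjusted p under 0.01 the siRNA effect held 1408 genes higher and 905 lower at 16 h and 1910 and 1240 at 48 h. The time effect then held 1175 and 1062 with control siRNA, 723 and 508 with lncFAM siRNA, and the interaction 43 and 91. With a log2 change of at least 1 the genes lower at 16 h were 1227, those higher at 48 h 2118 and those lower over time with control siRNA 1342. With no filter 3638 genes were lower at 48 h and the interaction held 434 and 1182, against 592 and 770 with DESeq2. With only the groups compared the time effect held 3699 genes higher with control siRNA and 824 with lncFAM siRNA. Protein-coding genes only gave 2183 genes higher at 48 h and 869 higher over time with lncFAM siRNA. Removing the length and GC trend gave 3682 genes higher and 3098 lower at 16 h, 3941 lower at 48 h, 2425 and 2113 over time with lncFAM siRNA and 738 and 906 in the interaction. The slope covariate gave 3189 lower at 16 h, 2624 and 2164 over time with lncFAM siRNA and 529 and 583 in the interaction. HNRNPL at 48 h was -0.095 with the trend removed (adjusted p = 0.58), MYBPC2 at 48 h -1.62 with the slope covariate (0.0581) and the lncFAM interaction 0.015 with limma-voom (0.994). The sarcomere list lost its call with an estimated correlation at 16 h (adjusted p = 0.554) and 48 h (0.835). Within 1 Mb of MYBPC2 the genes higher were 4 at 16 h and 13 at 48 h. Upper-quartile scaling moved the median of all genes to -0.101 over time with control siRNA and to 0.111 in the interaction. Genes that DESeq2 filters gave no value with it.

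The labels do not say that replicate numbers pair the samples. With each group's mean removed, libraries of equal number correlated across genes by 0.16, -0.04 and 0.25 between the siRNAs at 16 h and by -0.12, 0.24 and 0.44 at 48 h. Between the times they correlated by 0.35, -0.12 and 0.09 with control siRNA, and 0.04, 0.35 and 0.29 with lncFAM siRNA, the comparison in which each library matched its own number best. With a replicate block the interaction held 414 and 528 genes, and 110 genes were higher both over time and with lncFAM siRNA at 48 h.

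Leaving out 1 library at a time gave 1169 to 2169 genes lower at 16 h, 1944 to 3745 higher and 1596 to 4398 lower at 48 h. It gave 1334 to 3378 higher and 1166 to 2831 lower over time with control siRNA, 658 to 1953 lower with lncFAM siRNA, and 64 to 877 and 125 to 2326 in the interaction. MYBPC2 at 48 h lay between -2.033 and -1.462, HNRNPL at 48 h between -0.022 (without lncFAM 48 h replicate 3) and 0.306, and the lncFAM interaction between -0.811 and 0.367 (without lncFAM 16 h replicate 1). Overlap with the time effect at 48 h was 29 to 85 genes higher in both, 612 to 2004 higher then lower, 470 to 1311 lower then higher and 26 to 91 lower in both. At 16 h these were 141 to 433, 248 to 496, 186 to 454 and 120 to 416. Depth ranged from 63267897 to 256366866 counts, and at these depths most changes of 2-fold were missed in simulated data.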

Other observations

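The genes below lie outside the rule for naming genes and were chosen after their values were seen. All values are from the edgeR fit with 3 libraries per group, at 16 h and then at 48 h. HLA-B (log2 fold change 2.60 ± 0.247 and 3.62 ± 0.259), HLA-C (2.63 ± 0.267 and 3.51 ± 0.278) and their light chain B2M (1.62 ± 0.254 and 2.30 ± 0.259) rose with lncFAM siRNA. So did the peptide transporter TAP1 (3.19 ± 0.22 and 3.99 ± 0.228) and the immunoproteasome subunits PSMB8 (2.46 ± 0.224 and 3.32 ± 0.232) and PSMB9 (3.18 ± 0.268 and 4.62 ± 0.287). The class I activator NLRC5 rose too (2.74 ± 0.202 and 2.86 ± 0.203). CIITA, the activator of class II genes, was not called at 16 h (0.60 ± 0.229, adjusted p = 0.0888) or 48 h (0.54 ± 0.228, adjusted p = 0.103).

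Genes for 3 sensors of double-stranded RNA were looked up. RIGI (4.36 ± 0.613 and 3.69 ± 0.594) and IFIH1 (5.20 ± 0.57 and 5.26 ± 0.572), both already counted in the interferon-stimulated list, and TLR3 (5.73 ± 0.68 and 4.88 ± 0.655), which stands in no list, rose with lncFAM siRNA. IFNB1, a list member that encodes interferon beta, stood at 5.73 ± 1.0 CPM with lncFAM siRNA at 16 h, with no counts in the 3 control libraries. At 48 h it stood at 1.29 ± 0.84 CPM with lncFAM siRNA against 0.0277 CPM with control siRNA.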
